A study of Mus musculus with 12 samples.

How the data were processed

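Cerebella of 12-week and 29-week animals of both genotypes were the source of total RNA. Per the labels' protocols, RNA was isolated with TRIzol, purified on RNeasy columns, made into TruSeq libraries and sequenced as single-end reads of 50 bases on an Illumina HiSeq instrument. There were 12 libraries, 3 per condition, each from a pool of 3 mice. The labels name a genotype and an age for every library, which gives the 4 groups.

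The authors' processing used Bowtie 0.12.7, SAMtools 0.1.12a and Cuffdiff 1.3.0 with the mouse build mm10, per the submitters' processing notes, which give no role or order for these tools. The annotation, the filters and the normalization are not given in the sources used here. The deposited tables hold a normalized score, a whole number per gene and condition with no stated unit, so the 3 libraries of a condition were combined by the authors before deposit. The equal medians of 22 and the closely similar column sums were read as values normalized across conditions and rounded, not as read counts. Such a score hides the depth of each library, so no interval that needs counts was computed. Every gene row reached a value of 10 or more in at least 1 condition. Short RNAs and overlapping genes can receive unstable values in such tables, since a short transcript has few positions for a read and reads in shared exons can be assigned to either gene.

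The table of all genes had 7684 rows. Of these, 17 carried a number in the range of spreadsheet dates in place of a gene name, 1 such number occurring more than once, and were left out, which left 7667. Of the names 7357 were current symbols in the reference tables, 296 were older symbols and 14 were in neither. In 6 rows several genes were joined. Gene positions came from GENCODE M21 on the same assembly as mm10. The shorter deposited table of 99 genes held the same kind of score.

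The design fixed before the data were examined assumed FPKM values per library and a limma fit over the 12 libraries. It could not be applied, because the tables hold 1 value per condition, and the rule written for that case was used. For each gene a log2 ratio of condition values was computed with a pseudocount of 1 when one or both conditions reached a minimum of 5, and ratios of low genes are understated on this scale. Rounding ranges were computed by moving each value by 0.5. No test was made and no p-value is given. The comparisons were 92Q against wild type at each age, 29 against 12 weeks in each genotype, the difference of the genotype ratios between ages, and the overlap of the genotype effects. They share condition columns, so an unusual value in 1 condition enters several of them. Genes were counted at a threshold of 1.5-fold, which was chosen after the values were seen.

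The 27 gene lists were fixed before the data were examined, and 26 of them had a measured gene (373 genes in all). They were markers of Purkinje cells, granule neurons, interneurons, astrocytes and Bergmann glia, reactive astrocytes, microglia, oligodendrocyte precursors, endothelium, choroid plexus, meninges, blood and other brain regions, and genes of Purkinje calcium signalling, myelin, immediate early response, heat shock, endoplasmic reticulum stress, NAD metabolism, nuclear and mitochondrial respiration, the clock, p53, interferon, hereditary ataxia, voltage-gated channels, synapses and the SAGA complex. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins, which describes these values and is no test of the conditions.

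Genes were named by the rule fixed in advance for tables with 1 value per condition: per comparison the 10 largest log2 ratios in each direction, the genes of the deposited table of 99, Atxn7, and up to 4 members of each list with the largest ratios. Further list members were given as examples, and genes outside the rule were chosen after their values were seen.

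The ratio and list steps were tested on simulated data made from the real columns with 200 changed genes among 7667. The simulated noise was independent between genes, with an SD of 0.1 on the log2 scale per condition. The real 29-week genotype ratios had an SD of 0.18 over genes. Simulated list members were drawn at random, so the rates below do not cover marker lists whose members move together. For the 29-week genotype comparison, a true 1.5-fold change was recovered as a median of 1.50-fold for raised and 1.49-fold for lowered genes, and a 2-fold change as 1.95-fold and 1.88-fold. In that simulation 8.5% of unchanged lists fell outside the central 95% of random lists, and 100% of lists shifted by -0.3 were found below it. For the 12-week comparison 5% of unchanged lists fell outside. There a true 1.5-fold change was recovered as a median of 1.50-fold for raised and 1.44-fold for lowered genes. Raised or lowered genes near 1.5-fold can thus miss the threshold at either age. Alternatives were pseudocounts of 0.1 and 5, minimum values of 1 and 10, upper quartile and quantile scaling of the 4 columns, and, added later, scaling by median ratios, other fold thresholds and counts without particular gene classes. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.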

Results

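The study profiled cerebellar RNA of fxSCA7 92Q mice, a mouse model of spinocerebellar ataxia type 7 with 92 CAG repeats, and of wild-type littermates. Animals were taken at 12 and 29 weeks of age. Each of the 4 conditions had 3 sequencing libraries, and each library pooled the tissue of 3 mice, which gives 12 libraries. The deposited tables hold 1 value per gene and condition, so every value below is the authors' value for a condition. The comparisons have no replicate check, and the words higher and lower describe these 4 values alone. The values are whole numbers of a normalized score and the read depth behind them is unknown. The 4 condition columns had the same median of 22, and Mbp, a myelin protein gene, had the highest value in each. Rounding to whole numbers alone leaves a log2 ratio uncertain by 0.13 for a gene at 10 and by 0.06 for a gene at 22. Atxn7 itself was not analysed here, so the genotype labels were not checked against its expression.

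The first question was how the 92Q genotype relates to cerebellar expression at 12 weeks. Purkinje cell genes were lower in 92Q. Of 24 measured Purkinje cell markers 21 were lower and 2 were higher, with a median log2 ratio of -0.20, at percentile 0 of 10000 random gene lists of the same size and expression. Gng13, a G protein gamma subunit, was 641 in 92Q against 935 in wild type (log2 ratio -0.54). Pcp2, a Purkinje cell protein that acts on G protein signalling, was 1241 against 1661 (-0.42), Pcp4, a calmodulin regulator, was 1318 against 1749 (-0.41), and the calcium-binding protein Calb1 was 347 against 426 (-0.30). In the list of Purkinje calcium and mGluR1 signalling genes 22 of 30 measured members were lower and 7 higher (median -0.12, percentile 0). None of the members of these 2 lists reached a 1.5-fold difference at this age.

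Several other groups also stood apart at 12 weeks. Nuclear genes of the mitochondrial respiratory chain were lower in 33 of 35 members (median -0.10, percentile 0; -0.0686 after upper quartile scaling), and genes of endoplasmic reticulum stress were lower in 15 of 17 (median -0.14, percentile 0), among them the chaperone Hspa5 at 125 against 155 and the transcription factor Xbp1 at 96 against 111. Immediate early genes had a median of -0.13 (percentile 0.06), with Fos at 8 against 13 and Nr4a2 at 8 against 11. Granule neuron markers lay slightly above 0 (median 0.05, 13 of 22 higher; 0.0816 after upper quartile scaling), and the microglia median was 0.00 over 12 measured members.

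Few genes differed strongly at 12 weeks. Of 7660 genes with a value of 5 or more in one or both conditions, 6 were at least 1.5-fold higher in 92Q and 13 were at least 1.5-fold lower. These 19 were mostly of 3 kinds. Short noncoding RNAs and the ribosomal RNA precursor Rn45s (159 against 283) accounted for 8 of them. AF357426, a small nucleolar RNA, was listed at 0 in 92Q against 309 in wild type, DQ267102 was 71 against 206, Rmrp, the RNA of RNase MRP, was 7 against 40, Rpph1, the RNA of RNase P, was 6 against 25, AF357399 and AF357425 were 75 against 29 and 171 against 83, and Gm12238 was 9 against a value listed at 0. The Y-linked genes Eif2s3y and Ddx3y were 12 and 9 in 92Q and listed at 0 in wild type, while Xist, the X-inactivation transcript, was 30 against 66. Genes of the choroid plexus were lower: Ttr, the thyroid hormone carrier transthyretin, was 6 in 92Q against 336 in wild type, the potassium channel Kcnj13 was 2 against 7 and the chloride channel Clic6 2 against 5. Enpp2, the enzyme autotaxin, was 45 against 92 and the secreted augurin gene 1500015O10Rik 3 against 8. The choroid plexus list had a median of -1.21 over 4 measured members, of which 3 were lower and Otx2 was 10 in both. That median ranged from -0.65 with a pseudocount of 5 to -2.79 with a minimum value of 10. The meningeal list had a median of -0.24 over 6. Without these kinds of genes, a count added after the data were seen, 1 gene was at least 1.5-fold higher, the peptide transporter Slc15a2 at 14 against 8, and 4 were lower, Enpp2, 1500015O10Rik, Fos and the cytochrome oxidase subunit Cox6b2 (11 against 17). Enpp2 and 1500015O10Rik were, like Ttr and Kcnj13, lowest in 92Q at 12 weeks and highest in 92Q at 29 weeks, so this count is not free of that signal. Markers of brain regions outside the cerebellum had a median of -0.18 over 4 (percentile 0.215), with Tcf7l2 at 11 against 16, and oligodendrocyte precursor markers one of 0.14, higher in all 4 (percentile 99.9). Myelin genes had a median of -0.06 (17 of 26 lower, percentile 0.26), and -0.0139 after quantile normalization, inside the central 95% of random lists. The 12-week pools thus differed in Y-linked, Xist, choroid plexus and other marker signal in the same comparison in which the Purkinje genes were lower. The 92Q values had more Y-linked and less Xist signal than wild type at both ages, and 12-week wild type had no Y-linked signal. Genotype and the sex makeup of the pools therefore cannot be told apart.

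At 29 weeks the Purkinje genes were further below wild type. In this comparison 1 of the 3 libraries of 92Q has a library number apart from the other 29-week libraries, and its part in the condition value cannot be separated. Of the 24 Purkinje cell markers 22 were lower in 92Q and 2 were higher, the median log2 ratio was -0.51 (percentile 0), and 10 were at least 1.5-fold lower. Gng13 was 386 against 759 (-0.97), Pcp4 843 against 1432 (-0.76), Rgs8, a regulator of G protein signalling, 154 against 262 (-0.76), Arhgef33 33 against 58 (-0.80), Calb1 233 against 356 (-0.61) and Pcp2 871 against 1324 (-0.60). The 2 higher members were Nefh, a neurofilament subunit, at 73 against 66, and Stmn4 at 93 against 87. Pcp2 lies on mouse chromosome 8 at 3623371 to 3625545, Gng13 on chromosome 17 at 25717171 to 25719406 and Calb1 on chromosome 4 at 15881264 to 15908064 (mm10, GENCODE M21, whole protein-coding genes).

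The calcium and mGluR1 signalling list was lower in 26 of 30 members and higher in 1 at 29 weeks, with a median of -0.45 (percentile 0) and 11 members at least 1.5-fold lower. Itpr1, the IP3 receptor that releases calcium from the endoplasmic reticulum, was 190 in 92Q against 313 in wild type (-0.72). The calcium pump Atp2a3 was 42 against 70 (-0.72), Itpka, a kinase of IP3, 16 against 28 (-0.77), and the T-type calcium channel gene Cacna1g 34 against 52 (-0.60). Car8, which binds the IP3 receptor, was 167 against 263 (-0.65). Itpr1 lies on chromosome 6 at 108213096 to 108551109. The 2 Purkinje lists share 6 measured genes; without members that stand on any other list, an alternative chosen after the data were seen, the medians were -0.44 for the markers and -0.34 for the calcium list. The hereditary ataxia list, whose genes cause ataxia when mutated, had a median of -0.06 over 24 members (percentile 0.13). Its members Itpr1 and Car8 had the largest differences of that list, and both also stand on the calcium list.

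Other neuronal lists differed less at 29 weeks. Granule neuron markers had a median of -0.09 (16 of 22 lower, percentile 0.02), with none at 1.5-fold, and Chn2 at 255 against 300 was the lowest of them. Cerebellar interneuron markers had a median of -0.16 (9 of 11 lower, percentile 0). Among them Eomes, a transcription factor of unipolar brush cells, was 6 against 19 (-1.51), and Pvalb, which Purkinje cells express as well, was 580 against 734 (-0.34). Voltage-gated channel genes had a median of -0.06 (percentile 0.02) and synaptic vesicle and receptor genes of -0.03 (percentile 3.09), where the glutamate receptor Grm4 was 100 against 143 (-0.51).

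Microglia genes were higher in 92Q at 29 weeks. All 14 measured members of the microglia list were above wild type, 12 of them by at least 1.5-fold, with a median log2 ratio of 0.98 (percentile 100). The list names 25 genes, and a gene had a row only if it reached 10 in some condition. Lyz2, Cd68, Trem2 and Cx3cr1 reached 10 only in 92Q at 29 weeks, so their direction was fixed by that. The count and percentile include them. C1qa, C1qb, C1qc, Tyrobp and Csf1r were above 10 in every condition. The complement genes C1qa, C1qb and C1qc were 63 against 26, 65 against 34 and 61 against 28. The signalling adaptor Tyrobp was 37 against 12 (1.55), its partner receptor Trem2 13 against 5, the lysosomal glycoprotein Cd68 20 against 6, lysozyme Lyz2 22 against 3 (2.52), and the growth factor receptor Csf1r 19 against 12 (0.62). Of the reactive astrocyte list 4 genes were measured and all were higher, with Serpina3n, a protease inhibitor, at 21 against 4 (2.14), the intermediate filament Gfap at 235 against 95, Vim at 136 against 116 and Serping1 at 20 against 17. That list names 21 genes, and Serpina3n has a row only because it reached 10 in 92Q at 29 weeks. C1qa lies on chromosome 4 at 136895917 to 136898803, Lyz2 on chromosome 10 at 117277331 to 117282321 and Gfap on chromosome 11 at 102887336 to 102900912.

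The wider astrocyte and Bergmann glia list had a median of 0.04 over 21 members (percentile 72.2), in which Apoe was 1552 against 1062 (0.55) and Gdf10, a Bergmann glia factor, 106 against 130 (-0.29). Myelin genes had a median of 0.14 (21 of 26 higher, percentile 100), with Opalin at 26 against 18 and Mog at 60 against 46. The oligodendrocyte precursor list had a median of 0.12 over 4 members and the endothelial list of 0.05 over 7, both inside the central 95% of random lists. In the same condition the choroid plexus list was higher in all 6 members (median 1.32, 5 of them at least 1.5-fold), with Ttr at 1403 against 445, Kcnj13 at 19 against 7 and Sostdc1 at 12 against 3. The list names 13 genes. Kcnj13, Clic6, Kl and Sostdc1 have rows only because they reached 10 in 92Q at 29 weeks, so their direction was fixed by that. The meningeal list was higher in all 6 members (median 0.36), with Igfbp2 at 52 against 23, and the blood list in all 3 (median 0.52), with the beta globin row Hbb-b1,Hbb-bs at 147 against 106. The meningeal gene Slc13a4 and the globin row Hba-a1,Hba-a2 likewise reached 10 only in 92Q at 29 weeks. The Y-linked Eif2s3y was 15 against 6, and Xist was 25 against 63.

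Immediate early genes, which follow neuronal activity, were lower in 92Q at 29 weeks, with a median of -0.45 (9 of 11 lower, percentile 0) and 5 members at least 1.5-fold lower. Fos was 10 against 27 (-1.35), Nr4a1 11 against 24 (-1.06), Nr4a2 8 against 18, Nr4a3 5 against 12 and Dusp1 22 against 42, while Jun was 28 against 22. For Fos, Nr4a1, Nr4a2, Nr4a3 and Dusp1 the 29-week wild-type value was the highest of the 4 conditions. Within 92Q the list's median with age was 0.00. Neuronal activity was not measured. Circadian clock genes had a median of -0.13 (15 of 17 lower, percentile 0), with Per2 at 16 against 22 and Per1 at 34 against 43. The endoplasmic reticulum stress list had a median of -0.05 (percentile 0.555; -0.0790 after scaling by median ratios), with Xbp1 at 69 against 84 and Hspa5 at 88 against 104. Respiratory chain genes were higher in 32 of 35 members by small amounts (median 0.09, percentile 99.97).

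Among the remaining lists at 29 weeks, heat shock proteins had a median of 0.04 over 14 genes (percentile 74.0), with Hspb8 at 25 against 19. NAD metabolism and sirtuin genes had a median of 0.00 over 15 (percentile 29.6) and p53 targets one of 0.07 over 10 (percentile 84.0). The SAGA list, the chromatin complex that holds ataxin-7, had a median of 0.06 over 16 members (percentile 80.2), none of which was lower than in wild type. Markers of brain regions outside the cerebellum had a median of 0.05 over 4, where Th, the enzyme tyrosine hydroxylase, was 5 against 11. The interferon list had 1 measured gene, Ifi27 at 22 against 16, and the list of mitochondrially encoded genes had 0.

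Over all 7666 genes compared at 29 weeks, 41 were at least 1.5-fold higher in 92Q and 56 at least 1.5-fold lower, while 80.0% lay within 1.1-fold. The higher count includes genes that reached 10 only in 92Q at 29 weeks, such as Cd52, Mpeg1 and Ace, and could only be higher. The lower count includes Nr4a3, Th and Trib1, which reached 10 only in 29-week wild type and could only be lower. Outside the lists, Xist and the short RNAs, low ratios included those of the phosphatase Dusp5 (-0.94), Fam107b (-0.89) and Mdfi, an inhibitor of MyoD (-0.89). Among the highest were Cd52, a surface glycoprotein of immune cells, at 25 against 7, and the macrophage gene Mpeg1 at 15 against 5. The ceramide synthase Cers1 was 7 against 2 and Gdf1, which lies inside Cers1 on the same strand, 34 against 38, with sums of 41 and 40, so the value of Cers1 alone is uncertain. Short RNAs made up 5 of the 97 genes, with AF357426 at 100 against 321, AF357399 at 43 against 122 and DQ267102 at 67 against a value listed at 0. Raising the threshold to 2-fold, chosen after the data were seen, left 25 higher and 10 lower.

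**Figure D1:**
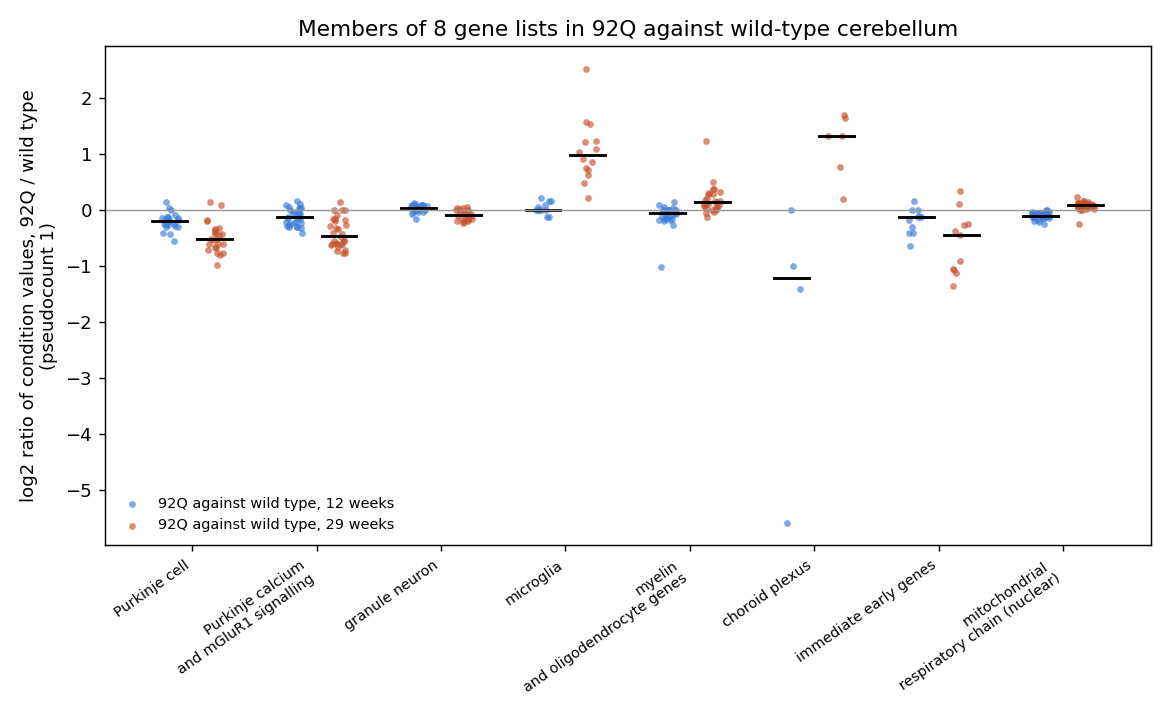
Each point is 1 measured gene of a list, with its log2 ratio of the 92Q over the wild-type condition value on the vertical axis (pseudocount 1), in blue at 12 weeks and in red at 29 weeks, and black bars give list medians. Purkinje medians lay at -0.20 and -0.51, microglia medians at 0.00 and 0.98, and choroid plexus medians at -1.21 and 1.32.

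**Figure D2:**
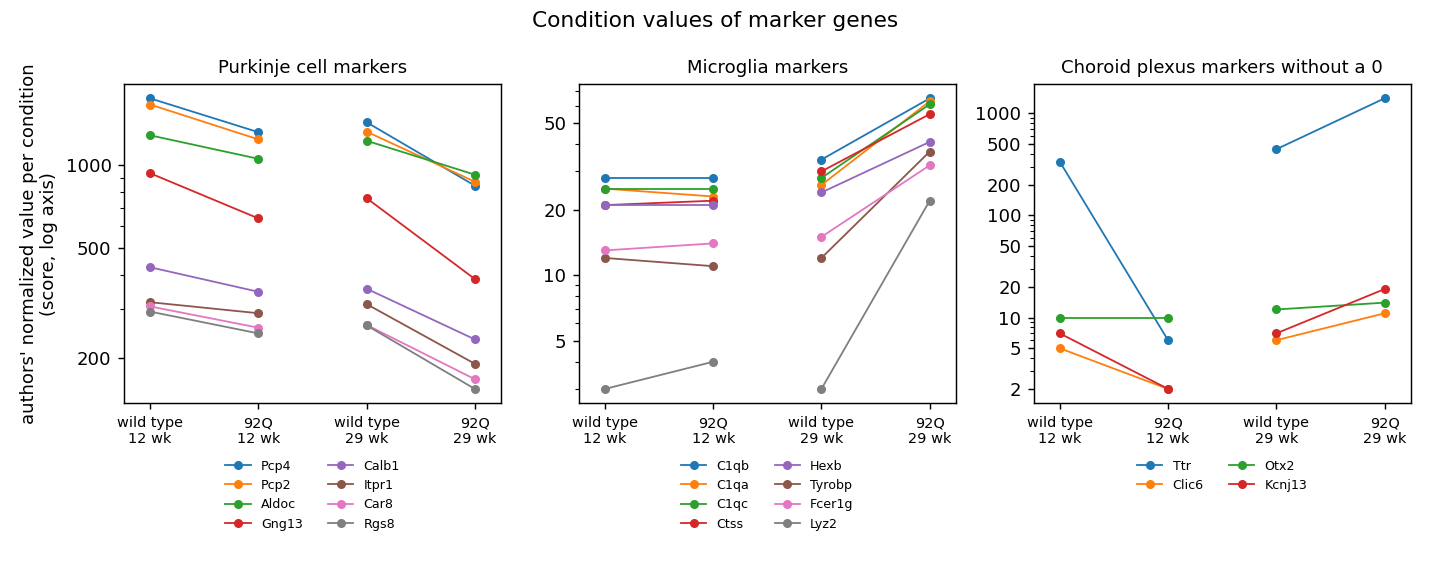
The authors' normalized condition values, on log axes, are drawn for 8 Purkinje cell markers, 8 microglia markers and the 4 choroid plexus markers with no value of 0, with lines joining wild type to 92Q of the same age. The Purkinje markers shown had the highest wild-type values at 12 weeks and the microglia markers the highest 92Q values at 29 weeks. They need not represent their whole lists. Pcp4 was 1749 and 1318 at 12 weeks and 1432 and 843 at 29 weeks, while Tyrobp was 12 and 11, then 12 and 37.

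A shorter table singled out 99 genes. In the authors' deposited table of 99 genes all 4 columns held the same values as the table of all genes. By the authors' deposited table, 26 genes were higher and 72 lower in 92Q at 29 weeks, 69 were lower at both ages, and 11 were higher at both ages. Those 72 genes had a median log2 ratio of -0.64 at 29 weeks and of -0.27 at 12 weeks in the authors' deposited table, and the 26 higher genes had medians of 0.86 and 0.02. The authors' deposited table contained 13 of the Purkinje cell markers, 14 of the calcium signalling list, 10 of the microglia list, 5 immediate early genes and 4 hereditary ataxia genes. The list was chosen on these samples by a rule not given in the sources used here, so it is not independent evidence of these directions. Large differences at 29 weeks outside it included Tyrobp, C1qa, C1qc, Gfap, Spp1, a secreted phosphoprotein (64 against 27), and the lysosomal protease Ctsd (298 against 180).

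The next question was what differed with age in wild-type animals. Between 12 and 29 weeks 17 genes were at least 1.5-fold higher and 11 at least 1.5-fold lower of 7663, or 9 and 7 with a pseudocount of 5. Circadian clock genes were higher at 29 weeks (14 of 17, median 0.31, percentile 100): Per2 was 22 against 10 (1.06), Per1 43 against 26 (0.70), Per3 16 against 11 and Hlf 58 against 43, while Arntl, which activates the Per genes, was 13 against 17. The sample titles give no hour of tissue collection, so its part in the clock values of any comparison here is unknown. Immediate early genes had a median of 0.42 (9 of 11 higher, percentile 100), with Fos at 27 against 13, Nr4a1 at 24 against 15 and Dusp1 at 42 against 26. The same 29-week wild-type values enter the genotype comparison at 29 weeks, so these are not separate results. Endoplasmic reticulum stress genes were lower (14 of 17, median -0.36, percentile 0), with Sdf2l1 at 11 against 18, Creld2 at 10 against 16, Hspa5 at 104 against 155 and Xbp1 at 84 against 111.

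Purkinje cell markers were slightly lower at 29 weeks in wild type (19 of 24, median -0.14, percentile 0.04, and -0.0643 at percentile 0.5 after quantile normalization), with Pcp2 at 1324 against 1661, and the calcium list lay within the central 95% of random lists (median -0.03). Cerebellar interneuron markers were higher (9 of 11, median 0.14, percentile 100), with Eomes at 19 against 16 and Pvalb the other way at 734 against 878. Microglia genes were higher in 12 of 13 (median 0.19, percentile 100), led by the protease Ctss at 30 against 21. Respiratory chain genes were lower in 33 of 35 (median -0.17), heat shock genes in 13 of 14 (median -0.13, and -0.0654 after quantile normalization, inside the central 95% of random lists). Fabp7, a fatty acid carrier of immature glia, was 12 against 22, and the insulin-degrading enzyme Ide 19 against 32. The synthase Cers1 was 2 against 13 while the overlapping Gdf1 was 38 against 28, with sums of 40 and 41, and carries the same uncertainty. Short RNAs and Rn45s made up 7 of these 28 genes, among them DQ267102, listed at 0 at 29 weeks against 206, and Rmrp at 1 against 40. The Y-linked Eif2s3y was 6 against 0 and Ddx3y 5 against 0, whereas Xist was 63 against 66. The sex makeup of the wild-type pools may thus differ between the ages as well. The choroid plexus list had a median of 0.24 over 5 genes, with Ttr at 445 against 336. Markers of brain regions outside the cerebellum were higher in all 4 measured genes (median 0.35, percentile 100), with Slc17a6 at 21 against 16 and Th at 11 against 8. The library numbers in the sample titles run in separate series for the 2 ages, so age and library series cannot be told apart.

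In 92Q animals 75 genes were at least 1.5-fold higher at 29 than at 12 weeks and 37 were at least 1.5-fold lower, of 7667, or 45 and 20 with a pseudocount of 5. The higher count includes genes with a row only because they reached 10 in 92Q at 29 weeks, such as Htr2c (13 against 5) and Ezr (11 against 7). Such genes could enter only as higher, so the larger number of higher genes is partly fixed by that. Microglia genes were higher in all 14 members (median 1.22, percentile 100), with C1qa at 63 against 23, Ctss at 55 against 22 and Laptm5 at 17 against 8. Among these 14, Lyz2, Cd68, Trem2 and Cx3cr1 have rows only because they reached 10 in 92Q at 29 weeks. Purkinje cell markers were lower in 22 of 24 (median -0.43, percentile 0), with Gng13 at 386 against 641, and calcium signalling genes in 26 of 30 (median -0.30). Granule neuron markers were lower in 21 of 22 (median -0.24, percentile 0), and Grm4, a presynaptic glutamate receptor of granule cells, was 100 against 187 (-0.90). Clock genes were higher (13 of 17, median 0.21), with Per2 at 16 against 10 and Per1 at 34 against 23, and the immediate early gene median was 0.00. Endoplasmic reticulum stress genes were lower in 13 of 17 (median -0.12), with Hspa5 at 88 against 125. Choroid plexus genes were among the largest differences, with Ttr at 1403 against 6, Kcnj13 at 19 against 2, and Kl and Sostdc1 at 14 and 12 against values listed at 0. The list's median was 3.22, and 2.37 without the genes listed at 0, and it ranged from 1.77 with a pseudocount of 5 to 5.05 with one of 0.1. That median includes Kcnj13, Clic6, Kl and Sostdc1, which have rows only because they reached 10 in 92Q at 29 weeks. The small nucleolar RNA AF357426 was 100 against a value listed at 0, and Enpp2, of the myelin list, was 238 against 45. The meningeal list had a median of 0.65, all 6 members being higher. Markers of brain regions outside the cerebellum had a median of 0.52 over 4 genes, with Slc17a6 at 24 against 14, Tcf7l2 at 19 against 11, Prox1 at 15 against 12 and Th at 5 against 7. Age and library series coincide here too.

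The last question was whether the genotype effect differed between ages. The difference of the log2 ratios, 29 weeks minus 12 weeks, was negative for 23 of 24 Purkinje cell markers (median -0.28, percentile 0) and for 29 of 30 calcium signalling genes (median -0.30, percentile 0). It was positive for all 12 microglia genes measured at both ages (median 0.85, percentile 100), led by Tyrobp at 1.66. Cd68 and Cx3cr1, among those 12, reached 10 only in 92Q at 29 weeks, which favoured a positive difference for them. Immediate early genes had a median of -0.38, with Dusp1 at -0.79 and Nr4a1 at -0.76, and their high 29-week wild-type values enter here too. Over 7659 genes the difference was at least 1.5-fold upward for 54 and downward for 20, or 32 and 13 with a pseudocount of 5. The upward count includes genes that reached 10 only in 92Q at 29 weeks, such as Ace and 1500015O10Rik. The downward count includes Nr4a3 and Th, which reached 10 only in 29-week wild type. Quantile normalization of the 4 columns gave 45 and 33, so that the upward share was 57.7% in place of 73.0%. Among genes with no value of 0, Ttr (7.24), Kcnj13 (2.74), 1500015O10Rik (2.42) and Enpp2 (2.24) had the highest differences, and AF357399 (-2.82) and AF357425 (-2.12) the lowest. The choroid plexus list had a median difference of 2.26 over 4 genes (1.42 with a pseudocount of 5, 3.73 with a minimum value of 10) and the meningeal list one of 0.73 over 6. Kcnj13 and Clic6, among those 4, reached 10 only in 92Q at 29 weeks.

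Few of the 1.5-fold genes were shared between the 2 ages. The overlap was taken over the 7659 genes that passed the minimum at both ages, which left 12 of the 13 lower and all 6 higher genes at 12 weeks and 56 lower and 34 of the 41 higher genes at 29 weeks. Lower at both were 3 genes, AF357426, Xist and Fos, where independent lists of 12 and 56 genes would share 0.0877. Higher at both were the 2 Y-linked genes Eif2s3y and Ddx3y, from lists of 6 and 34. At a log2 threshold of 0.32, chosen after the data were seen, 20 genes were lower at both ages against 1.19 for independent lists, and they included Pcp2, Pcp4, Gng13, Eomes, Nr4a2, Nr4a3 and Sdf2l1. Of the 56 genes that were 1.5-fold lower at 29 weeks, 50 were already below wild type at 12 weeks and 4 above, with a median of -0.27, whereas 36.7% of all genes were below. The 34 genes of the overlap that were 1.5-fold higher at 29 weeks had a median of 0.00 at 12 weeks, with 11 above wild type and 14 below. Across all genes, which are not independent replicates, the 2 genotype effects correlated with a Pearson r of 0.0857 and a Spearman rho of 0.104.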

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

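The tests of explanations in this part were chosen after the results were seen. The differences between ages given here were not tested, since each condition has 1 value.

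Some lists and genes lay on opposite sides of wild type at the 2 ages. The difference of the genotype effects, 29 weeks minus 12 weeks, had a median of 2.26 for the choroid plexus list, 0.73 for the meningeal list, 0.19 for the myelin list, 0.17 for nuclear respiratory chain genes and -0.16 for granule neuron markers. It was 7.24 for Ttr, 2.74 for Kcnj13, 2.42 for 1500015O10Rik, 2.24 for Enpp2 and 1.78 for Clic6. For the small nucleolar RNAs AF357399 and AF357425 it was -2.82 and -2.12. The myelin median at 12 weeks became -0.0139 after quantile normalization, inside the central 95% of random lists.

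Choroid plexus genes were lowest in 92Q at 12 weeks and highest in 92Q at 29 weeks, in that order in 5 of the 6 list members against 3.53% of all genes. Y-linked and Xist signal differed between the genotypes at both ages, so the sex makeup of the pools probably differed too. Sex makeup as the cause of this order would need Y-linked signal to differ between the 92Q pools as the choroid plexus genes do. The log2 ratio of the Y-linked signal between them was 0.31, against a list median of 3.22. Choroid plexus tissue carried along in dissection and an effect of genotype and age on the choroid plexus would give that same order, so the count decides nothing, and these explanations cannot be told apart.

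Microglia genes were higher in 92Q at 29 weeks, when choroid plexus, meningeal and blood genes were higher too. At 12 weeks Ttr differed by -330, while the summed values of the 14 microglia genes differed by 3; choroid plexus tissue with the same proportion of both at each age would have given -85.1. With sex makeup as the cause and the same effect at both ages, the 12-week microglia median would be 0.93, and it was 0.00. Both comparisons assume a fixed proportion between ages and have no spread between pools to be held against, so neither explanation is excluded. Microglia number or state with the 92Q genotype and age, or cells of blood or meninges, may also account for the pattern and were not tested.

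Purkinje genes were lower in 92Q at 29 weeks. Added RNA of cells other than Purkinje cells and granule neurons would lower the granule neuron markers of the same pools about as much as the Purkinje markers. The Purkinje median was -0.51 and the granule median -0.0934, which argues against such RNA as the whole cause. Added RNA of granule neurons themselves would not lower granule markers, so this comparison cannot decide on it. Sex makeup with the same effect at both ages would give a median of -0.21, but with 1 value per condition this comparison does not exclude it. A smaller share of Purkinje cells would lower all their markers by 1 factor. The markers spread with an SD of 0.27 on the log2 scale, but many are also expressed elsewhere, so fewer cells and lower expression per cell cannot be told apart. The effect of the 92Q genotype stays among the open explanations.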

How the results depend on the processing

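The changes of fold threshold, the scaling by median ratios, the counts over whole rounding ranges and the lists without shared members were chosen after the data were seen. No result in any setting turned its direction among lists outside the random range or genes at 1.5-fold; over all settings 3989 values stayed within rounding or within 1.5 times a count and 765 moved. Genes higher and lower with age in wild type numbered 9 and 7 with a pseudocount of 5, 7 and 5 at 2-fold, 11 and 7 without short RNAs, sex-linked, choroid plexus and meningeal genes, and 9 and 7 over the whole rounding range, against 17 and 11. With age in 92Q, 75 and 37 became 45 and 20 with a pseudocount of 5 and 32 and 3 at 2-fold, and the lower count was 24 over the rounding range. For the difference between ages, 54 and 20 became 32 and 13 with a pseudocount of 5, 18 and 6 at 2-fold and 30 and 11 over the rounding range, and quantile normalization gave 33 downward. At 2-fold the 29-week genotype counts were 25 and 10. Without short RNAs, sex-linked, choroid plexus and meningeal genes the 12-week counts were 1 and 4 against 6 and 13, and 0 genes were higher and 1 lower at both ages; at a log2 threshold of 0.32 these were 5 and 20 with those genes kept. A higher pseudocount shrinks ratios of low genes, and the other settings on counts except quantile normalization drop or add genes by construction. Purkinje marker medians moved with a pseudocount of 5 to -0.42 at 29 weeks, -0.12 with age in wild type and -0.40 with age in 92Q; with quantile normalization to -0.15 at 12 weeks, -0.57 at 29 weeks, -0.0643 and -0.48 with age, and -0.35 for the difference between ages; with upper quartile scaling to -0.16 at 12 weeks and -0.11 with age in wild type; with median ratios to -0.53 at 29 weeks; and without shared members to -0.44 at 29 weeks and -0.37 with age in 92Q. The calcium list moved to -0.09 at 12 weeks with upper quartile scaling and -0.0879 with quantile normalization, and at 29 weeks to -0.41 with a pseudocount of 5, -0.48 with median ratios or quantile normalization and -0.34 without shared members, and its difference between ages to -0.36 with quantile normalization. Granule medians became 0.0816 with upper quartile scaling, 0.0565 with quantile normalization and 0.0391 without shared members at 12 weeks, and -0.12 with median ratios and -0.10 with quantile normalization at 29 weeks. With a pseudocount of 5, microglia medians were 0.85 at 29 weeks and 1.04 with age in 92Q, and immediate early genes had 0.30 with age in wild type. Choroid plexus medians were -0.65 with a pseudocount of 5, -1.71 and -2.79 with minimum values of 1 and 10 and -0.77 with quantile normalization at 12 weeks, and 0.96 with a pseudocount of 5 at 29 weeks; few members pass each minimum. Endoplasmic reticulum stress genes with age in wild type had -0.29 with quantile normalization and -0.31 without shared members; the cause was not tested. Scaling to equal medians changes nothing because all 4 medians are 22. Not run, because the tables hold 1 value per condition, were leaving out replicates, filters and weights per library, limma settings, gene set tests and count models. No paired analysis was possible because the columns carry no replicate. Depth is unknown, and rounding limits genes near the minimum most.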

Other observations

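The gene groups in this part were chosen after the values were seen. Lysosomal genes outside the microglia list were higher in 92Q at 29 weeks in 25 of 27 members (median log2 ratio 0.18), and had a median of 0.00 at 12 weeks. The group was picked with members such as Ctsd and Ctsz already seen to be high, and microglia (median 0.98), choroid plexus (1.32) and meningeal markers (0.36) were higher in the same condition. Ctsd, an aspartic protease, was 298 in 92Q against 180 in wild type, Ctsz 41 against 25, the progranulin gene Grn 34 against 25 and Man2b1 11 against 8, while Psap was 720 against 676. The metallothioneins Mt1, Mt2 and Mt3 were 1266 against 1065, 586 against 431 and 521 against 463 at 29 weeks, and each was lower than wild type at 12 weeks.

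Ribosomal protein genes went opposite ways at the 2 ages, with a median of -0.10 over 21 genes at 12 weeks and 0.11 at 29 weeks, close to the medians of -0.10 and 0.09 of the nuclear respiratory chain list. The difference was not tested.

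Cers1, a ceramide synthase, was 13 and 2 in wild type at 12 and 29 weeks and 16 and 7 in 92Q. Gdf1, which lies on the same strand inside Cers1 on chromosome 8 (100% of its length), was 28 and 38, and 23 and 34. The sums of both were 41, 40, 39 and 41, so the separate values of Cers1 and Gdf1 are uncertain.

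The rows named by date numbers held values between 10 and 268, and the row with the highest values was 268 and 241 in wild type and 252 and 223 in 92Q at 12 and 29 weeks. Gene names were not assigned to them. The astrocyte and Bergmann glia list had 21 of 22 genes measured and names Sept4, a symbol that reads as a date. The row with the highest values carries the number 43712, the spreadsheet form of the date that Sept4 reads as. That list member is thus very probably among the rows left out.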
